A study of Homo sapiens with 28 samples.

How the data were processed

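RNA-seq gene counts of 28 libraries of NCI-H1975, a human lung adenocarcinoma line whose growth depends on the receptor kinase EGFR, were used. Per the labels, total RNA was purified from frozen cells with a column kit and DNase, and libraries were made with a strand-specific total RNA kit. Cultured cells received a kinase inhibitor at 1 uM or the solvent DMSO for 12 h, while the xenograft libraries carry a treatment time of 6 h; their dose is not given in the sources used here. The values are whole-number counts of reads per gene, not normalized, as deposited by the authors. Per the file headers, counts were made with featureCounts 1.6.2, summed by gene name over GENCODE 28 on the genome build GRCh38.p12, from 1 merged alignment file per library. The recorded command holds no option for strand, read pairs or reads that map to several places. STAR and FastQC are named without a version or settings, per the submitters' processing notes. Because the command sets no strand, reads of a gene and of an overlapping or antisense gene were counted without telling them apart. Genes with near-identical copies, such as ribosomal protein, histone, HLA, keratin 6 and CT45A genes, can gain or lose reads by the handling of reads with several matches, and their values are uncertain.

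Libraries were grouped by the labels for the CRISPR target (SAFE, a control, or RB1), the treatment and the kind of sample. The runs of title numbers fall into 2 parts, which were treated as separate batches. Part 1 holds vehicle and osimertinib libraries of 4 clones labelled SAFE and 4 clones labelled RB1. Part 2 holds SAFE clone 1 only, with 2 libraries each of erlotinib, gefitinib, osimertinib and dacomitinib in culture and of vehicle and osimertinib in xenografts. Replicates are clones in part 1 and libraries of 1 clone in part 2, and p-values measure the spread within groups. All groups of a fit share this spread. In part 1 the tests of SAFE clones therefore also carry the spread among clones labelled RB1, and the main fits ignore the clone pairs. The 4 SAFE vehicle libraries lay closer to each other (r of log levels across genes, which are not independent, 0.9927 to 0.9948) than those of the 4 clones labelled RB1 (0.9751 to 0.9877). Whether the SAFE clones grew from separate single cells is not given in the sources used here, so n = 4 can stand for fewer independent clones. No step that parts reads of host and tumour cells in the xenografts is given there either. Intervals from counts and limits from counts of 0 cover counting error only. No pair of libraries within a group was close enough to be 1 library deposited 2 times: over 38 pairs the lowest chi-square per degree of freedom of the counts was 2.9.

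The 56832 gene symbols of the files were kept as given, and no line lacked a gene name. Gene types came from GENCODE 29 by symbol, which 29681 symbols matched, among them 18772 protein-coding ones, while 27151 had no match. Start and end of a gene are those in the files on GRCh38.p12, and 148 symbols lie on several chromosomes.

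Differences were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment over all genes of a fit, and a gene was called at an adjusted p under 0.05. Fits were made over the 16 libraries of part 1, the 8 cultured libraries of part 2, the 4 xenograft libraries, the 12 libraries of part 2, the SAFE cultures of part 1 with the xenografts, and the 16 cultured SAFE libraries of both parts. In the last fit the part was an additive term, so that osimertinib, present in both parts, links erlotinib, gefitinib and dacomitinib to vehicle. Fold changes are log2 values ± SE, and levels are CPM of the totals scaled within a fit, as mean ± SD. Levels in the figures and among the flagged values were scaled over all 28 libraries together, so they can differ from those of a fit. The share of the osimertinib response that another inhibitor kept was 1 plus the slope through the origin of the inhibitor minus osimertinib difference in part 2 on the osimertinib change in SAFE clones of part 1, over genes called with at least a 2-fold change. A fold against a group with a count of 0 was computed against 3 counts over that group, and a ratio with 1 to 3 counts is given with its exact binomial 95% interval.

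Before the data were examined, 33 gene lists were fixed: ERK output, immediate early and AP-1 genes, the EGFR family and its ligands, other receptor kinases, RB-E2F regulators, E2F and DNA replication, G2 and mitosis, FOXO and growth arrest, the BCL2 family, p53 targets, cholesterol synthesis, fatty acid synthesis, glycolysis, hypoxia, ATF4 and amino acid genes, ribosome biogenesis, lysosome and autophagy, interferon response, antigen presentation, NF-kB and cytokines, mesenchymal, epithelial, YAP and TEAD, lung lineage, neuroendocrine, chromatin regulators, replication histones, markers of fibroblasts, of endothelium, of myeloid and lymphoid cells, and of blood, muscle, fat and skin, mitochondrial transcripts, and abundant noncoding RNAs. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The genes named were RB1, a fixed panel (EGFR, DUSP6, SPRY4, ETV5, CCND1, MYC, E2F1, MCM2, CCNE2, MKI67, CDKN1B, BCL2L11, ERBB3 and HMGCS1), up to 6 highest and 6 lowest called protein-coding genes per comparison with a mean log2 CPM of at least 1 and no overlap of the compared libraries, and up to 2 per list each way. Some genes that meet these rules are not reported here. Marker lists for T cells (27 genes) and cartilage (20 genes) were written after some of these genes had been seen.

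Clone labels pair the vehicle and osimertinib libraries of a clone. The deviations of the paired libraries from their group means correlated across genes, which are not independent, at 0.84 to 0.88 in the 4 RB1 clones and at 0.37, 0.01, 0.38 and 0.31 in SAFE clones 1 to 4. Alternatives were a clone or replicate block, other scalings (RLE factors, totals only, and totals without mitochondrial and the 20 most abundant genes), no filter or a stricter filter, DESeq2 1.42.0, limma-voom, other sets of libraries in the fit, and each library left out in turn. R 4.3.3, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

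The steps were tested on simulated counts with 200 changed genes. At 1.5, 2 and 4-fold, the SAFE osimertinib step recovered 34.3%, 71.6% and 98.5% of changed genes over 18158 genes, and 4.2% of its calls were unchanged genes. The interaction step recovered 9.0%, 43.3% and 89.4% over 18167 genes with 6% of calls unchanged. The osimertinib against dacomitinib step recovered 46.3%, 82.1% and 100% over 17874 genes with 7.3% unchanged. The step for dacomitinib through osimertinib recovered 35.8%, 79.1% and 97% over 18076 genes with 4.7% unchanged. The xenograft step recovered 50.7%, 82.1% and 100% over 16139 genes with 5.5% unchanged. The xenograft difference step recovered 49.3%, 77.6% and 95.5% over 18499 genes with 8.1% unchanged, and the step between the parts 53.7%, 91% and 100% over 18707 genes with 4.7% unchanged. Retained shares of 0, 0.25 and 0.75 were estimated as 0.035, 0.276 and 0.76 over 983 simulated genes. Both parts were simulated with the same means and the same osimertinib effect, so a bias from a difference between the parts could not show. Libraries were drawn independently, without effects shared by the libraries of a clone. The rates can differ in data with clone pairs or with far more changed genes.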

Results

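Gene expression was measured by RNA-seq in 28 libraries of NCI-H1975 cells, a lung adenocarcinoma line with mutant EGFR, under inhibitors of this receptor kinase. Part 1 held 16 cultured libraries, from 4 clones labelled SAFE (control) and 4 clones labelled RB1, each with vehicle and with osimertinib for 12 h. Part 2 held 12 libraries of SAFE clone 1: 2 cultures each with erlotinib, gefitinib, osimertinib or dacomitinib for 12 h, and 2 xenografts each with vehicle or osimertinib for 6 h. The total count per library was 34346161 to 41496782 in part 1, 23366888 to 27495312 in the cultures of part 2 and 19500563 to 23763075 in the xenografts. On GRCh38.p12, EGFR lies on chromosome 7 from 55019021 to 55211628, RB1 on chromosome 13 from 48303726 to 48599436, and DUSP6, a phosphatase induced by ERK, on chromosome 12 from 89347232 to 89353271. CCND1 (cyclin D1) lies on chromosome 11 from 69641087 to 69654474, MKI67 (proliferation antigen Ki-67) on chromosome 10 from 128096659 to 128126385, and HMGCS1 (HMG-CoA synthase of cholesterol synthesis) on chromosome 5 from 43289395 to 43313512.

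The transcript of the targeted gene, RB1, was not lower in the clones labelled RB1. Its level was 11.18, 10.37, 10.78 and 9.48 CPM in SAFE vehicle clones 1 to 4 and 8.24, 10.4, 8.59 and 7.71 CPM with osimertinib. In clones 1 to 4 labelled RB1 it was 21.38, 7.92, 14.24 and 21.95 CPM with vehicle and 19.91, 9.98, 16.23 and 21.81 CPM with osimertinib. RB1 was higher in the clones labelled RB1 under osimertinib (0.99 ± 0.27, adjusted p = 0.00809, n = 4 and 4) and did not pass the test under vehicle (0.66 ± 0.27, adjusted p = 0.0657). A transcript that is still made can carry a frameshift, which gene counts do not show, so directions below are drawn by the labels.

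Osimertinib, an irreversible anilinopyrimidine inhibitor of EGFR, lowered the output of the ERK pathway and the cell cycle program in SAFE clones. SPRY4, a feedback inhibitor of ERK signalling, fell from 21.1 ± 0.73 to 0.517 ± 0.204 CPM (log2 change -5.34 ± 0.47, adjusted p = 1.82e-07, n = 4 and 4). DUSP6 changed by -3.72 ± 0.59 (adjusted p = 8.85e-05), CCND1 by -4.13 ± 0.26 (adjusted p = 5.85e-09), and FOSL1, an AP-1 subunit, by -4.39 ± 0.15 (adjusted p = 8.73e-12). MKI67 fell from 447.5 ± 35.8 to 34.6 ± 7.62 CPM (-3.69 ± 0.21, adjusted p = 1.78e-09). The neurotrophin receptor NGFR rose from 0.229 ± 0.0755 to 57.5 ± 5.88 CPM (7.96 ± 0.60, adjusted p = 3.54e-08). Of 19262 genes tested, 9306 changed, 4520 up and 4786 down, among them 2200 up and 1600 down by at least 2-fold. In a fit of these 8 libraries alone 12323 of 18119 genes changed.

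Ranks given here hold among protein-coding genes with a mean log2 CPM of at least 1 and no overlap of the compared libraries. The other genes with the greatest increases were the phosphatase DUSP15 (7.32 ± 0.66), the sulfotransferase SULT1C2 (5.84 ± 0.61), the kinase PNCK (5.37 ± 0.36), the interferon-inducible TRIM22 (4.99 ± 0.63) and the transcription factor MAF (4.90 ± 0.60). The greatest decreases under the same filter were in MYEOV (-5.46 ± 0.30), SPRY4, ANGPTL4, an inhibitor of lipoprotein lipase (-4.89 ± 0.31), FOSL1, the helicase PIF1 (-4.26 ± 0.24) and MFSD2A, a lysolipid transporter (-4.24 ± 0.31). In the panel, the ETS factor ETV5 changed by -3.95 ± 0.30, MYC by -0.99 ± 0.21 and EGFR itself by -0.73 ± 0.12. E2F1 and CCNE2 (cyclin E2), both central to S phase entry, each changed by -2.36 ± 0.18, and the helicase subunit MCM2 by -1.89 ± 0.19. CDKN1B, the cyclin-dependent kinase inhibitor p27, rose by 0.82 ± 0.18, with an adjusted p of 0.00133. The receptor ERBB3 rose from 29.1 ± 3.75 to 88.3 ± 14.1 CPM (adjusted p = 0.00313), and HMGCS1 rose by 1.13 ± 0.17 (adjusted p = 4.76e-05). BCL2L11, which encodes the cell death protein BIM, was higher in each of the 4 clones, at 28.9 ± 1.54 against 23.9 ± 0.78 CPM, but did not pass in the fit of all 16 libraries (0.28 ± 0.33, 95% interval -0.43 to 0.98, adjusted p = 0.519). It passed with clones as a block (adjusted p = 0.00627) and in a fit of these 8 libraries alone (adjusted p = 0.00139).

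By fixed list, all 50 E2F and DNA replication genes, all 33 G2 and mitosis genes and all 32 ribosome biogenesis genes fell, with the same counts adjusted over the list alone. Examples were the replication factors MCM10 (-4.04 ± 0.16) and CLSPN (-3.50 in log2), the topoisomerase TOP2A (-3.81 ± 0.17) and the RNA polymerase III subunit POLR3G (-1.90). Of 21 ERK output genes 17 fell and none rose, of 25 RB-E2F regulators 18 fell and 2 rose (CDKN2B, a kinase inhibitor, by 1.57 ± 0.12), and none of these counts moved adjusted over the list alone. Genes of the FOXO and growth arrest list rose, 22 of 27 with 1 down (PIK3IP1, an inhibitor of PI3K, 3.54 ± 0.28, and CCNG2, an unconventional cyclin, 3.36 ± 0.11). So did 23 of 30 lysosome and autophagy genes with 1 down (GPNMB, a lysosomal glycoprotein, 3.45 ± 0.32). These 7 lists passed camera with an estimated correlation, at adjusted p of 2.03e-04 (E2F), 0.00512 (mitosis), 0.0252 (ribosome biogenesis), 0.0128 (ERK), 0.0217 (RB-E2F), 7.49e-04 (FOXO) and 2.68e-04 (lysosome). With clones as a block the estimated-correlation values were 0.0605 for mitosis, 0.142 for RB-E2F regulators and 0.142 for ribosome biogenesis.

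Cholesterol synthesis genes rose, 18 of 24 with none down (19 of 24 adjusted over the list alone), for example the sterol reductase TM7SF2 (2.53 ± 0.28) and lanosterol synthase LSS (2.10 ± 0.13). Interferon response genes rose in 20 of 38 and fell in 2 (OAS2, an antiviral enzyme, 2.34). Antigen presentation genes rose in 14 of 21 and fell in 1 (15 and 1 adjusted over the list alone; HLA-E 1.15). Epithelial genes rose in 12 of 25 and fell in 2 (JUP, a junction protein, 2.20). ATF4 and amino acid genes rose in 13 of 26 and fell in 5 (NUPR1 2.59). Chromatin regulators fell in 21 of 46 and rose in 7 (8 adjusted over the list alone; UHRF1, which maintains DNA methylation, -3.10). These 6 lists passed camera at the preset correlation and lost the call otherwise, at adjusted p = 0.383, 0.41, 0.347, 0.41, 0.479 and 0.41 with an estimated correlation, in the order given.

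The remaining lists did not pass camera. Members up and down were 5 and 6 of 22 immediate early genes (EGR1 -3.94 ± 0.33), 3 and 7 of 14 EGFR family genes (the ligand AREG -2.59), and 7 and 4 of 20 other receptor kinases (AXL -1.93 ± 0.12). They were 3 and 5 of 17 BCL2 family genes (BMF 3.67 ± 0.52, BCL2 -1.20), 6 and 3 of 19 p53 targets, and 4 and 5 of 12 fatty acid synthesis genes. Further counts were 2 and 11 of 21 glycolysis genes, 8 and 4 of 20 hypoxia genes (10 and 5 adjusted over the list alone), and 8 and 4 of 25 NF-kB genes (the cytokine CSF2 -5.09 ± 0.41). Lineage lists gave 4 and 4 of 24 mesenchymal genes, 10 and 7 of 22 YAP and TEAD genes, 3 and 2 of 15 lung lineage genes and 4 and 1 of 10 neuroendocrine genes, and 10 and 5 of 22 replication histones moved (11 and 5 adjusted over the list alone). The BCL2 family had a median of -0.01 while its test pointed up (adjusted p = 0.992). Marker lists gave 3 and 0 of 16 for fibroblasts (adjusted p = 0.0808, and with clones as a block 0.0158, or adjusted p = 0.419 with an estimated correlation) and 1 and 1 of 9 for endothelium. They gave 1 and 0 of 6 for myeloid and lymphoid cells (0 and 0 adjusted over the list alone), and 1 and 0 of 5 for blood, muscle, fat and skin. With clones as a block more members passed, 11 up and 1 down of 16 fibroblast markers, 12 and 6 of 24 mesenchymal genes, 7 and 0 of 13 mitochondrial transcripts and 30 and 3 of 38 interferon genes. Abundant noncoding RNAs rose in 4 of 9 and mitochondrial transcripts in 2 of 13, and mitochondrial genes took 5.88 to 6.96% of counts in SAFE vehicle and 8.8 to 9.71% in SAFE osimertinib libraries.

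**Figure D1:**
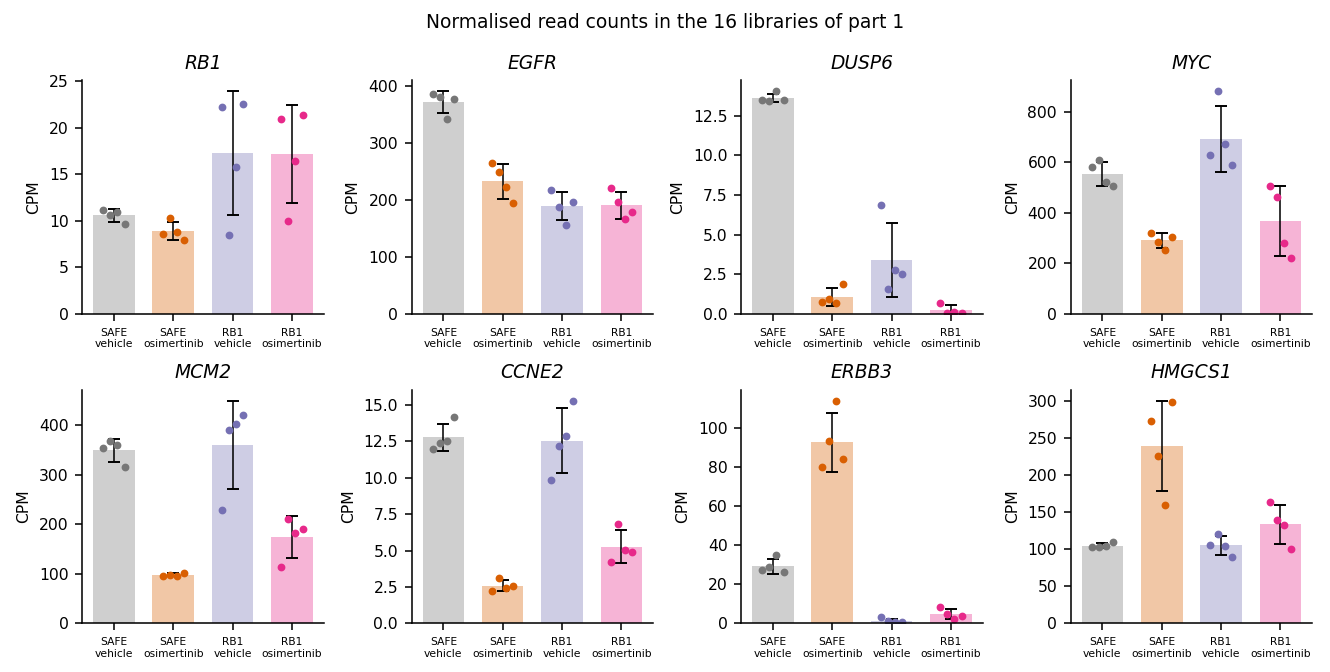
Level of 8 genes in the 16 cultured libraries of part 1, in CPM. Bars are group means, error bars SD and points the 4 clones of a group; DUSP6, MCM2 and CCNE2 are lower with osimertinib under both labels, ERBB3 is lower in clones labelled RB1, and RB1 itself is not lower in clones labelled RB1.

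In the clones labelled RB1, osimertinib lowered ERK output and cell cycle genes. SPRY4 changed by -6.62 ± 0.57 (adjusted p = 2.80e-07, n = 4 and 4), the early growth response factor EGR1 by -6.21 ± 0.38, the EGFR ligand AREG by -5.09 ± 0.32, FOSL1 by -4.22 ± 0.15 and MYEOV by -5.33 ± 0.34. NGFR rose by 6.25 ± 0.61, DUSP15 by 5.67 ± 0.69, BPIFB4 by 5.36 ± 0.43, GPNMB by 5.10 ± 0.36 and PNCK by 5.09 ± 0.38. MAF was at least 17.5-fold higher and the focal adhesion gene TNS4 was lower by a ratio of 22.2 (95% interval 5.8 to 189). MKI67 changed by -2.61 ± 0.20, E2F1 by -1.60 ± 0.18, CCNE2 by -1.22 ± 0.17 and MCM2 fell from 345.8 ± 83.8 to 172.3 ± 42.3 CPM (adjusted p = 3.89e-04). The panel genes DUSP6 (-3.86 ± 0.65), ETV5 (-4.03 ± 0.30), CCND1 (-3.86 ± 0.26) and MYC (-0.88 ± 0.21) fell, and CDKN1B (0.66 ± 0.18) and ERBB3 (1.83 ± 0.45) rose. RB1 (0.02 ± 0.27, adjusted p = 0.958), EGFR (0.04 ± 0.12, adjusted p = 0.811), BCL2L11 (-0.35 ± 0.34, adjusted p = 0.427) and HMGCS1 (0.38 ± 0.17, adjusted p = 0.0775) did not pass. These tests ignore the clone pairs. Scaled over all libraries, BCL2L11 fell in each clone, from 29.23, 18.32, 13.58 and 11.25 to 26.3, 13.82, 8.23 and 7.34 CPM. HMGCS1 rose in each, from 105.42, 120.6, 104.32 and 89.78 to 163.35, 138.65, 132.46 and 99.84 CPM.

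Of 19262 genes 8192 changed, 4331 up and 3861 down, and 5172 in a fit of these 8 libraries alone. All 50 E2F genes, all 33 mitosis genes and all 32 ribosome biogenesis genes fell, as did 16 of 21 ERK output genes, and 21 of 27 FOXO genes (22 adjusted over the list alone) and 22 of 30 lysosome genes rose. These lists kept their calls with an estimated correlation, at adjusted p of 6.38e-04, 0.00399, 0.0206, 0.00399, 0.00147 and 6.38e-04, and with clones as a block the values for mitosis and ribosome biogenesis were 0.0569 and 0.133. Cholesterol synthesis genes rose in 5 of 24 and fell in 3 (adjusted p = 0.415). Interferon response genes rose in 21 of 38 (adjusted p = 0.00326, and adjusted p = 0.575 with an estimated correlation) and abundant noncoding RNAs in 7 of 9 (0.00179, and adjusted p = 0.217 with an estimated correlation). With clones as a block the epithelial list passed (0.0744 without and 0.00706 with the block), as did fibroblast markers (0.152 and 0.00519), and chromatin regulators no longer did (0.0319 and 0.0557). Both new calls were lost with the block and an estimated correlation, at adjusted p = 0.467 and 0.439 with an estimated correlation.

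The osimertinib change differed between the labels for cell cycle genes, which fell less in clones labelled RB1, and for cholesterol genes, which rose less. The interaction was 1.14 ± 0.24 for CCNE2 (adjusted p = 0.0252, 4 clones each), 1.48 ± 0.20 for MCM10 and 1.33 ± 0.14 for the primase PRIM1 (adjusted p = 3.85e-04). It was 0.94 for the RB family member RBL1 and 0.78 ± 0.17 for EGFR (adjusted p = 0.0292). The squalene enzymes SQLE (-1.12) and FDFT1 (-0.97) and CCNG2 (-1.20 ± 0.14, adjusted p = 7.08e-04) had negative interactions. Of the 50 E2F genes 25 had a positive interaction and none a negative one (46 and 0 adjusted over the list alone; adjusted p = 7.90e-04 with an estimated correlation). Of 33 mitosis genes 9 were positive (28 adjusted over the list alone; adjusted p = 0.054 with an estimated correlation), and of 24 cholesterol genes 3 were negative (17 adjusted over the list alone; adjusted p = 0.0428 with an estimated correlation). With clones as a block the cholesterol call was lost (adjusted p = 0.245 with an estimated correlation).

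In total 292 genes had an interaction, 224 positive and 68 negative, and DESeq2 gave 690, 431 positive and 259 negative. Leaving out any single SAFE library gave 108 to 179 genes, leaving out RB1 vehicle 2 gave 184 and leaving out RB1 osimertinib 1 gave 503. The split moved with single libraries: it was 148 positive and 137 negative without RB1 vehicle 1, 101 and 95 without RB1 vehicle 4, and 338 and 291 without both libraries of RB1 clone 1. Under the filter for named genes, the greatest interactions were in the lectin CD22 (2.35 ± 0.35), WNT10B (2.24 ± 0.34), GRAMD1B (2.21 ± 0.45), G0S2 (2.18 ± 0.42), ALOXE3 (2.06 ± 0.32) and the ectonucleotidase NT5E (2.01 ± 0.46, adjusted p = 0.0387). The lowest were in the sodium channel subunit SCNN1A (-2.91 ± 0.33, adjusted p = 4.52e-04), EGR1 (-2.27 ± 0.46), KRT16 (-2.16 ± 0.43), CYP26B1 (-2.13 ± 0.46), SLC16A4 (-2.02 ± 0.36) and ZNF513 (-1.87 ± 0.28). E2F1 (0.77 ± 0.25, adjusted p = 0.165), MCM2 (0.89 ± 0.26, adjusted p = 0.108), MKI67 (1.08 ± 0.27, adjusted p = 0.0581) and HMGCS1 (-0.75 ± 0.24, adjusted p = 0.151) did not pass. With clones as a block 2768 genes passed, 1806 positive and 962 negative, among them all 292 and the genes E2F1, MCM2, MKI67, HMGCS1 and BCL2L11 (-0.70 ± 0.11, adjusted p = 0.00112). In that fit the E2F list stood at 46 and 0 (adjusted p = 0.0478 with an estimated correlation), and mitosis at 30 and 0 (adjusted p = 0.264 with an estimated correlation). Cholesterol synthesis stood at 1 positive and 21 negative, and the lung lineage list passed camera (0.508 without and 0.00137 with the block), a call lost with an estimated correlation (adjusted p = 0.283 with an estimated correlation).

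Across the 3800 genes changed at least 2-fold in SAFE clones, the change in clones labelled RB1 was 0.74 of that in SAFE clones. Across genes changed at least 2-fold in clones labelled RB1, the change in SAFE clones was 0.947 of that in clones labelled RB1. Both called 6725 genes and 6699 in the same direction, 3292 up against 1016 for independent lists and 3407 down against 959; r across all genes, which are not independent, was 0.84. Of the 292 interaction genes 242 changed less in clones labelled RB1.

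**Figure D2:**
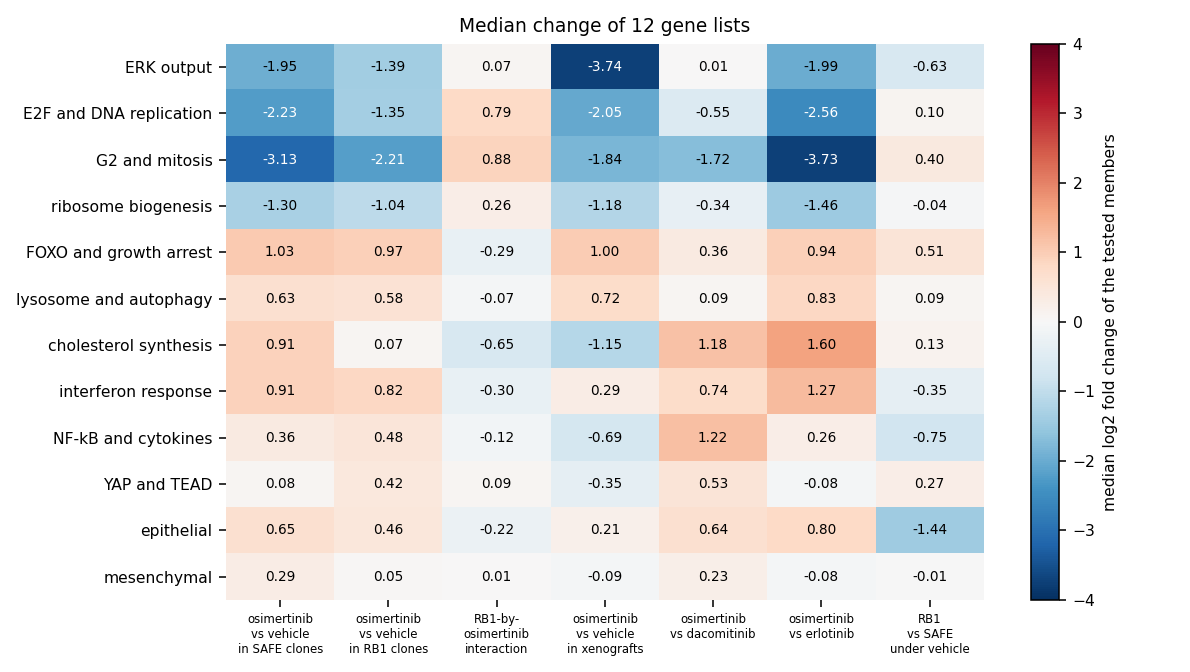
Median log2 fold change of 12 fixed gene lists in 7 comparisons, with lists as the vertical and comparisons as the horizontal axis. E2F and mitosis genes have negative medians in each osimertinib against vehicle comparison, -2.23 and -3.13 in SAFE clones and -1.35 and -2.21 in clones labelled RB1.

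Under vehicle, clones labelled RB1 held less RNA of epithelial genes than SAFE clones, a direction drawn by label because the RB1 transcript was not lower. ESRP1, a splicing regulator of epithelial cells, stood at 0.146 against 48.7 CPM (-8.36 ± 0.28, adjusted p = 4.51e-11, n = 4 and 4), and RAB25, an epithelial trafficking gene, was at least 148-fold lower. ERBB3 stood at 1.29 against 29.1 CPM (-4.48 ± 0.47, adjusted p = 3.44e-06), and EGFR at 183 against 370 CPM (-1.02 ± 0.12, adjusted p = 1.14e-05). ZEB2, a repressor of epithelial genes, was higher (2.33 ± 0.20), while the keratin KRT8 was also higher (0.50 ± 0.14). Of 25 epithelial genes 18 were lower and 1 higher (19 and 1 adjusted over the list alone; adjusted p = 0.00646 with an estimated correlation).

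Other large differences by label were TMPRSS15 (9.65 ± 1.80, adjusted p = 6.15e-04, at 35.9 ± 44.0 CPM in clones labelled RB1), the lipoprotein receptor OLR1 (ratio 147, 26 to 5840), SCARA5 (5.55 ± 1.07), TRIM29 (5.14 ± 1.07, at 2.29 ± 2.88 CPM in clones labelled RB1 and highest in clone 1), GGT5 (5.05 ± 0.90) and BMP5 (5.01 ± 0.95). Lower were GABRE (at least 638-fold), SCEL (ratio 1080, 193 to 42600), the peroxidase PXDN (ratio 835, 149 to 33000), TMEM30B (-8.48 ± 0.26) and NPTX2 (-8.37 ± 0.62). NF-kB and cytokine genes were lower in 13 of 25 and higher in none (CXCL5 -6.53 ± 0.83, PTGS2 -6.31 ± 0.76), with adjusted p = 0.661 with an estimated correlation. Chromatin regulators were higher in 24 of 46 and lower in 4 (29 and 5 adjusted over the list alone; adjusted p = 0.54 with an estimated correlation). ERK output genes were lower in 11 of 21 (12 adjusted over the list alone; adjusted p = 0.692 with an estimated correlation), DUSP6 by -2.03 ± 0.54. Of cell cycle genes, E2F1 (-0.11, adjusted p = 0.668), MCM2 (-0.01 ± 0.18, adjusted p = 0.974) and CCNE2 (-0.08) did not pass and MKI67 was higher (0.54 ± 0.19, adjusted p = 0.0349). Of 50 E2F genes 11 were higher and 5 lower (10 and 3 adjusted over the list alone). In all 7449 genes differed, 3758 higher and 3691 lower in clones labelled RB1. Mitochondrial genes took 6.21, 3.79, 3.62 and 3.77% of counts in RB1 vehicle clones 1 to 4 and 9.3, 5.97, 5.49 and 4.03% with osimertinib.

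Under osimertinib the clones labelled RB1 held more cell cycle transcripts and fewer cholesterol synthesis transcripts than SAFE clones. MKI67 was higher by 1.62 ± 0.19 (adjusted p = 1.08e-05, n = 4 and 4), CCNE2 by 1.07 ± 0.17, MCM2 by 0.88 ± 0.18 and E2F1 by 0.66 ± 0.18. Of 50 E2F genes 42 were higher (44 adjusted over the list alone; adjusted p = 0.0452 with an estimated correlation), as were 32 of 33 mitosis genes (adjusted p = 0.272 with an estimated correlation). HMGCS1 differed by -0.80 ± 0.17 (adjusted p = 0.00131), INSIG1 by -2.33 and SQLE by -1.95. Of 24 cholesterol genes 14 were lower (15 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation). BCL2L11 differed by -1.08 ± 0.34 (adjusted p = 0.017) and ERBB3 by -4.25 ± 0.44. Epithelial genes were lower in 17 of 25 (GRHL2 -8.64 ± 0.30; adjusted p = 0.00502 with an estimated correlation). In all 8197 genes differed, 4717 higher and 3480 lower.

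At 1 uM for 12 h, ERK output and cell cycle genes stood far lower with osimertinib and dacomitinib than with erlotinib and gefitinib. Erlotinib and gefitinib are reversible 4-anilinoquinazolines, dacomitinib is an irreversible anilinoquinazoline and osimertinib an irreversible anilinopyrimidine. All libraries came from 1 line with mutant EGFR, so the mode of binding was not tested as a cause of this difference. DUSP6 stood at 14.6 ± 1.13 CPM with erlotinib, 13.3 ± 0.742 with gefitinib, 1.26 ± 0.112 with osimertinib and 0.719 ± 0.0346 with dacomitinib (n = 2 each). In the same order MKI67 stood at 540.8 ± 39.2, 606.8 ± 35.2, 18.5 ± 5.10 and 107.9 ± 6.17 CPM. Osimertinib relative to erlotinib gave -4.62 ± 0.10 for CCND1, -4.75 for SPRY4, -4.87 ± 0.18 for MKI67 and -5.07 ± 0.11 for the ribonucleotide reductase subunit RRM2 (adjusted p = 9.12e-09). NGFR was higher by 8.97 ± 0.23 and HMGCS1 by 2.50 ± 0.09. In that comparison all 50 E2F genes, all 33 mitosis genes and 18 of 21 ERK output genes (19 adjusted over the list alone) were lower with osimertinib. Of 24 cholesterol genes 22 and of 38 interferon genes 33 were higher, and 10329 of 18422 genes differed in all. With a term for the library sets in the plot of marker sums, the interferon call was lost (adjusted p = 0.031 without and 0.0635 with the term, each with an estimated correlation). The call of FOXO genes was lost too (0.0375 without and 0.0575 with the term). E2F and mitosis (0.00365 each) and ERK output and cholesterol genes (0.0126 each) kept theirs. Against gefitinib 10461 genes differed, with NGFR at 8.74, TOP2A at -5.28 and HMGCS1 at 2.26. In that comparison no list kept a call with the term and an estimated correlation, and the adjusted p of E2F genes went from 3.17e-04 to 0.107 with an estimated correlation.

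Between the irreversible inhibitors, mitotic genes were lower and cholesterol and cytokine genes higher with osimertinib than with dacomitinib. MKI67 differed by -2.54 ± 0.17 (adjusted p = 1.08e-05, n = 2 and 2), TOP2A by -2.79 ± 0.13 and PIF1 by -3.02 ± 0.19. HMGCS1 was at 425.2 ± 35.1 against 104.6 ± 0.251 CPM (2.02 ± 0.09, adjusted p = 2.11e-06). NGFR differed by 7.66 ± 0.20 (107 ± 11.8 against 0.520 ± 0.219 CPM), DUSP15 by 5.54 ± 0.21, KRT81 by 3.80 ± 0.13 and the interleukin IL6 by 2.83 ± 0.13. Of the ERK targets, DUSP6 differed by 0.81 ± 0.22 (adjusted p = 0.026), ETV5 by 0.62 ± 0.14 and CCND1 by -0.78 ± 0.09. SPRY4 did not pass (0.52, 95% interval -0.06 to 1.10, adjusted p = 0.223). Differences of MYC (-0.17 to 0.19), E2F1 (-0.22 to 0.18), CDKN1B (-0.10 to 0.30), BCL2L11 (-0.63 to 0.11), ERBB3 (-0.04 to 0.63) and EGFR (-0.94 to -0.10, adjusted p = 0.0673) did not pass after adjustment, given as 95% intervals. KRT1 was at least 179-fold lower with osimertinib. Its level was 10.04 and 13.29 CPM in the dacomitinib libraries, 9.97 CPM in erlotinib library 1 and 0 CPM in erlotinib library 2. The dacomitinib libraries, erlotinib library 1 and osimertinib library 6 carried the cartilage markers shown in the plot of marker sums. KRT1 stood at 0 CPM in both osimertinib libraries, so it did not follow these markers in library 6. A term for the library sets cannot cover this difference.

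Of 33 mitosis genes 31 were lower with osimertinib than with dacomitinib, and of 50 E2F genes 32 lower and 3 higher (33 and 3 adjusted over the list alone). Of 24 cholesterol genes 21 were higher (22 adjusted over the list alone), as were 28 of 38 interferon genes (32 adjusted over the list alone), 19 of 25 NF-kB genes (20 so adjusted), 15 of 22 YAP and TEAD genes (17) and 15 of 25 epithelial genes (16). Of 32 ribosome biogenesis genes 16 were lower (23 adjusted over the list alone). Adjusted p with an estimated correlation was 8.97e-04, 0.0281, 0.00158, 0.0283, 0.00502, 0.00994, 0.0281 and 0.0281 in that order. Osimertinib library 5 carried T cell transcripts (sum 29.14 CPM) and the dacomitinib libraries did not (3.58 and 3.71). With a term for the library sets in the plot of marker sums, interferon (adjusted p = 0.0991 with an estimated correlation), epithelial (0.0577) and ribosome biogenesis genes (0.0577) lost the call. The p53 targets, which passed without the term (0.0489), lost the call too (0.0991). Mitosis, E2F, NF-kB and YAP genes (0.0289 each) and cholesterol genes (0.0236) kept it. ERK output genes went both ways, 4 up and 5 down of 21 (adjusted p = 0.639). The count of 4865 genes, 2598 higher and 2267 lower, was 1750 higher and 3624 lower with scaling by totals only, which moves the median of all genes to -0.127. Mitochondrial genes took 6.69 and 11.45% of counts in the osimertinib libraries and 4.48 to 6.0% with the other inhibitors, and 7 of 13 mitochondrial transcripts were higher than with dacomitinib (12 adjusted over the list alone). Leaving out dacomitinib library 1 or 2 gave 1971 or 2094 genes, and leaving out osimertinib library 5 gave 7280.

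Erlotinib and gefitinib differed from each other in few genes. By the retained share, both kept almost none of the osimertinib response (0.001 and 0.018), so few differences do not show a shared mode of action. At this depth 7 of 18422 genes differed, all lower with gefitinib, and edgeR gave 1059 at an unadjusted p of 0.05. They were ADM2 (-1.28 ± 0.11, adjusted p = 0.004, n = 2 and 2), CHAC1 (-1.37 ± 0.15), KLHDC7B (-1.18 ± 0.12), and PCK2 (-1.17 ± 0.09). The others were the serine synthesis enzyme PHGDH (-0.94 ± 0.08), the pseudokinase TRIB3 (-0.84 ± 0.08) and, chosen after its values were seen, SESN2 (-0.82, adjusted p = 0.029). ATF4 and amino acid genes were lower in 4 of 26 (21 adjusted over the list alone; adjusted p = 0.00159 with an estimated correlation), and with the term for library sets in 1 (adjusted p = 0.0138 with an estimated correlation). The 95% interval of the gefitinib minus erlotinib difference was -0.39 to 0.12 for DUSP6, -0.50 to -0.03 for SPRY4 and -0.31 to 0.07 for CCND1. It was -0.17 to 0.50 for MKI67, -0.35 to 0.48 for EGFR and 0.03 to 0.44 for HMGCS1, with adjusted p of 0.835 or above for these genes. Leaving out gefitinib library 1 or 2 gave 0 genes, erlotinib library 1 gave 1 and erlotinib library 2 gave 24, and without a filter on low counts 123 genes passed.

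Dacomitinib relative to erlotinib lowered SPRY4 (-5.28), MYEOV (-4.82), EGR1 (-4.54) and DUSP6 (-4.33) and raised SULT1C2 (4.67) and the amino acid transporter SLC7A8 (3.74). In all 9731 genes differed, 4780 higher and 4951 lower (median of all genes 0.016), against 6319 higher and 3574 lower under scaling by totals only (median 0.182). No list kept a call with the term and an estimated correlation (E2F 0.00289 without and 0.0978 with the term). Against gefitinib 9945 genes differed, 4952 higher and 4993 lower, and 6352 higher and 3739 lower with totals only. This comparison follows the library sets in the plot of marker sums completely, and 6277 genes passed with a term for them. There 19 of 21 ERK output genes, all 50 E2F genes and all 33 mitosis genes were lower with dacomitinib, each with adjusted p = 0.00359 with an estimated correlation and 0.0758 with the term. So were 18 of 25 NF-kB genes (adjusted p = 0.0228 with an estimated correlation; 14 genes and 0.071 with the term), and 12 of 24 cholesterol genes were higher (14 adjusted over the list alone; adjusted p = 0.0996 with an estimated correlation). In this comparison COL2A1 (ratio 598, 204 to 2900), KRT1 (567, 101 to 22400) and KRT5 (322, 57.4 to 12800) were higher, but the gefitinib libraries carried T cell markers and the dacomitinib libraries cartilage markers. With the term COL2A1 and KRT1 no longer passed and their signs reversed.

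Set on 1 scale, dacomitinib kept 0.744 of the osimertinib response (range over 4 library pairs 0.728 to 0.760, 3547 genes), erlotinib 0.001 (-0.023 to 0.025) and gefitinib 0.018 (-0.002 to 0.038). The scale takes osimertinib to act with the same size in both parts. This cannot be checked, because part 2 held no cultured vehicle. Osimertinib cultures differed between the parts in 9950 genes, and the range over pairs, which share libraries, does not cover this. Linked to vehicle through osimertinib, dacomitinib changed 8313 of 20114 genes, lowering SPRY4 (-5.84 ± 0.40), DUSP6 (-4.51), ETV5 (-4.55) and MKI67 (-1.12 ± 0.23). It raised MAF (4.85 ± 0.22), GPNMB (4.29 ± 0.17), BMF (4.15), ERBB3 (1.33) and BCL2L11 (0.57 ± 0.16, adjusted p = 0.00808). Of 50 E2F genes 49 fell, of 21 ERK output genes 18 fell (20 adjusted over the list alone). The split was 4170 higher and 4143 lower, and 5345 and 3038 with totals only. Erlotinib changed 482 genes and gefitinib 649 by the same link. DUSP6 did not pass with either (-0.14, interval -0.88 to 0.61, and -0.28, interval -1.03 to 0.47), and HMGCS1 fell with both (-1.30 ± 0.22 and -1.07 ± 0.22). Linked values also carry the difference of osimertinib between the parts, for HMGCS1 365.8 and 436.85 CPM in part 2 against 159.56 to 298.51 in part 1. By level HMGCS1 stood at 66.69 and 71.29 CPM with erlotinib and 80.66 and 87.13 with gefitinib, against 102.31 to 109.47 with vehicle. MKI67 stood at 100.68 and 108.99 CPM with dacomitinib against 404.13 to 486.58 with vehicle. Vehicle and the reversible inhibitors never stood in the same part: without the term for part the counts were 2316 and 2493. SERPINB2, a protease inhibitor, stood at 2.94 and 2.65 with the term and reversed without it. Leaving out osimertinib library 5 gave 2141 and 3258 genes, leaving out osimertinib library 4 gave 1098 for gefitinib, and with clone 1 alone in part 1 the counts were 62 and 66. The splits were 388 higher and 94 lower for erlotinib and 517 and 132 for gefitinib, with totals only 286 and 122, and 352 and 157, and without mitochondrial and the 20 most abundant genes 260 and 142, and 314 and 188.

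**Figure D3:**
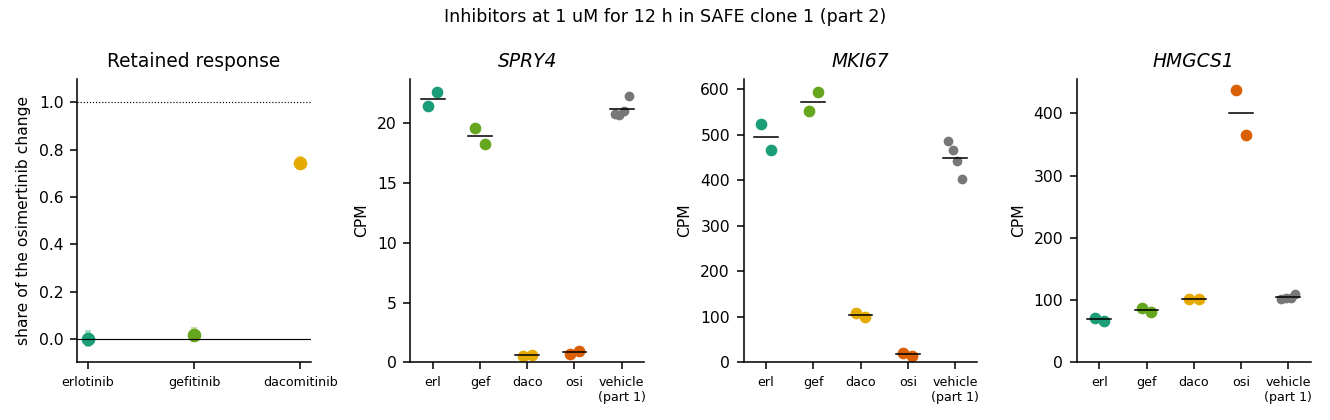
Retained share of the osimertinib response for 3 inhibitors (point, with the range over 4 library pairs), and the level of SPRY4, MKI67 and HMGCS1 per cultured library of part 2 and per SAFE vehicle library of part 1, in CPM scaled over all libraries together. Dacomitinib sits at 0.744, erlotinib at 0.001 and gefitinib at 0.018. The range does not cover a difference of the osimertinib response between the parts.

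In xenografts, 6 h of osimertinib lowered ERK output and cell cycle genes, raised BCL2L11 more than in culture and lowered cholesterol synthesis genes, most of which rose in culture. By list, none of these changes kept its call with an estimated correlation (adjusted p = 0.0868 for ERK, E2F and mitosis genes and 0.106 for cholesterol genes). BCL2L11 stood at 73.7 ± 1.06 against 20.2 ± 2.03 CPM (1.86 ± 0.10, adjusted p = 7.17e-07, n = 2 and 2), and HMGCS1 at 41.7 ± 0.208 against 191.6 ± 25.5 CPM (-2.20 ± 0.11, adjusted p = 5.68e-07). The difference from the 12 h culture response, which was tested directly, was 1.61 ± 0.11 for BCL2L11 (adjusted p = 5.84e-08), -3.31 ± 0.24 for HMGCS1, 1.26 ± 0.14 for EGFR and 1.83 ± 0.21 for MKI67. DUSP6 changed by -5.63 ± 0.23, SPRY4 by -6.12 ± 0.22, ETV5 by -5.67 ± 0.20, E2F1 by -3.74 ± 0.13 and MKI67 by -1.88 ± 0.10, while ERBB3 rose by 1.68 ± 0.10 and EGFR by 0.50 ± 0.09. Time, tissue setting, part and clones (all SAFE clones in culture, clone 1 in xenografts) differ between these tests. The xenograft dose is not given in the sources used here, and the design does not separate these factors.

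Highest in the xenograft response were the inositol kinase IP6K3 (6.30 ± 0.49), CYP4F3 (6.07 ± 0.32), SH2D3C (4.74 ± 0.29), N4BP2L1 (4.64 ± 0.28) and the potassium channel KCNQ1 (4.51 ± 0.34). FGFBP1 was lower by a ratio of 138 (38 to 1150). Of 24 cholesterol genes 20 fell and 2 rose (DHCR7 -2.39; adjusted p = 0.106 with an estimated correlation), and 10 of 12 fatty acid genes fell (SCD -2.68; adjusted p = 0.212 with an estimated correlation). All 49 E2F genes, all 33 mitosis genes and all 32 ribosome biogenesis genes fell, as did 20 of 21 ERK output genes, each with adjusted p = 0.0868 with an estimated correlation. Of 27 FOXO genes 23 rose (PDK4 4.32, PIK3IP1 3.52; adjusted p = 0.212 with an estimated correlation). Of 16921 genes 9767 changed, 4842 up and 4925 down, and the difference from culture passed for 5454 genes. By that difference 23 of 24 cholesterol genes were lower (adjusted p = 0.0667 with an estimated correlation), as were 9 of 12 fatty acid genes (10 adjusted over the list alone; adjusted p = 0.0155 with an estimated correlation). Of 33 mitosis genes 31 had fallen less in xenografts (adjusted p = 0.0155 with an estimated correlation). NGFR (-7.21 ± 0.70), KRT81 (-5.75 ± 0.36) and DUSP15 (-5.42 ± 0.66), raised in culture, had lower changes in xenografts. Called genes shared with the SAFE culture response numbered 6073 of 16061, 5710 in the same direction, 2534 up against 1115 for independent lists and 3176 down against 1336.

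The summed myeloid and lymphoid markers were 208 and 298 CPM in xenograft vehicle and 335 and 559 CPM in xenograft osimertinib libraries, against 11 to 45 CPM in cultures. Of 6 such markers 4 rose with osimertinib (5 adjusted over the list alone; adjusted p = 0.61 with an estimated correlation), the integrin ITGAM by 3.31 ± 0.26. The leukocyte gene PTPRC stood at 0 to 0.092 CPM in these 4 libraries. The sum of blood, muscle, fat and skin markers went from 230.19 and 87.42 CPM with vehicle to 841.87 and 2021.56 CPM with osimertinib. Most of it was KRT5, at 164.84 and 55.75 CPM with vehicle and 805.1 and 1979.15 CPM with osimertinib. No step that parts reads of host and tumour cells is given in the sources used here, so xenograft values can hold both. Under osimertinib, xenografts against cultures of part 2 differed in 12084 genes, with KRT5 (10.65 ± 1.00), TRIM29 (9.91 ± 0.37) and SIRPB2 (at least 166-fold) higher. Lower were the stretch-responsive ANKRD1 (-7.78 ± 0.18), NPR1 (ratio 432, 77.3 to 17100) and CYP1A1 (ratio 248, 84.5 to 1200). Interferon genes were higher in 36 of 38 (adjusted p = 0.33 with an estimated correlation), as were antigen presentation genes in 21 of 22 (adjusted p = 0.366 with an estimated correlation). Hypoxia genes were higher in 14 of 20 (17 adjusted over the list alone; adjusted p = 0.0381 with an estimated correlation), and 22 of 24 cholesterol genes were lower (adjusted p = 0.00407 with an estimated correlation). The split was 6457 higher and 5627 lower (median of all genes -0.007), and 5176 and 7346 with totals only (median -0.194).

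The same treatment, osimertinib in SAFE cultures, differed between the parts in 9950 genes, 4064 higher and 5886 lower in part 2 (5108 and 4634 with totals only). Ribosomal protein genes led: RPL7 stood at 800 against 4.22 CPM (7.57 ± 0.13, adjusted p = 1.02e-17, n = 2 and 4), RPS27 differed by 7.08, RPL21 by 6.27, RPS28 by 6.22 and RPS3A by 5.82, and the proteasome gene PSMC1 by 6.26. SERPINB2 (-4.48 ± 0.28), the mitotic PRC1 (-3.23), C19orf33 (-2.94) and the importin IPO4 (-2.62) were lower in part 2. MKI67 differed by -1.05. Of 50 E2F genes 45 were lower (adjusted p = 0.00623 with an estimated correlation), and 14 of 24 cholesterol genes were higher (16 adjusted over the list alone; adjusted p = 0.784 with an estimated correlation).

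**Figure D4:**
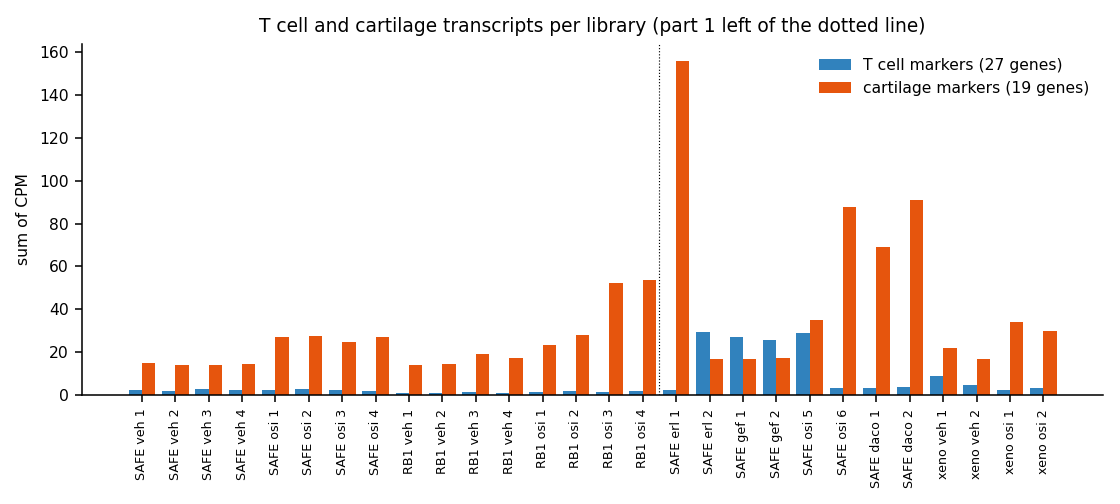
Sum of T cell markers and of cartilage markers, in CPM, in each library. T cell sums are 25.62 to 29.46 in erlotinib 2, gefitinib 1 and 2 and osimertinib 5 and at most 3.71 in the other cultures of part 2, where cartilage sums are 69.19 to 155.97.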

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

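The splits of the libraries, the slope test below and the values given here were planned, and the count without both libraries of RB1 clone 1 was chosen only after the result was seen. Among 92 groups of 4 values tested, 8 held a value far from the other 3, where chance gives such a value in about 1 of 20 groups, or 4.6 here. Of these 8, 6 fell in clone 1 labelled RB1.

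With vehicle, RB1 clone 1 stood apart in its mitochondrial share of counts (6.21% against 3.62 to 3.79% in the other clones), MCM2 (228.63 against 390.1 to 420.24 CPM), the sum of endothelial markers (40.36 against 4.77 to 8.38 CPM) and the sum of blood, muscle, fat and skin markers (26.06 against 28.71 to 29.23 CPM). With osimertinib it stood apart in DUSP6 (0.71 against 0.06 to 0.1 CPM) and in endothelial markers (56.45 against 9.42 to 15.59 CPM). In SAFE vehicle, DUSP6 in clone 3 (14.03 against 13.42 to 13.51 CPM) and E2F1 in clone 4 (100.52 against 112.87 to 114.36 CPM) were the values far from the rest.

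The osimertinib response differed between clones labelled RB1 and SAFE clones in 292 genes, and in 629 without both libraries of RB1 clone 1. Of the 35 splits of the 8 clones into groups of 4, 1, the real one, gave as many, and the highest of the others gave 0. The share of 1 in 35 is the smallest this test can give, and it does not cover SAFE clones that share an origin. The other splits mix labels that differ in 7449 genes under vehicle, which widens the spread within groups and can lower their counts. All splits were fitted without the clone block. For these reasons the test does not exclude chance. For E2F and DNA replication genes, a smaller response of all genes to osimertinib and a difference in these genes cannot be told apart by this test. The slope of 0.74 over the 3800 genes changed at least 2-fold in SAFE clones was removed (0.746 over all genes). Their median then stayed at 0.227 above 0 in log2, between the bounds set for the 2 outcomes, with 43 of 50 above 0. Over genes changed at least 2-fold in clones labelled RB1, the change in SAFE clones was 0.947 of theirs. The slope thus depends on how genes are chosen, and the residuals with it. Residual medians were 0.088 for mitosis, -0.354 for ERK output and -0.466 for cholesterol synthesis genes. Residuals above 0 numbered 22 of 33, 4 of 21 and 2 of 24, so this 1 slope did not describe the last 2 lists.

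The response to osimertinib differed between xenografts at 6 h and SAFE cultures at 12 h in 5454 genes, by a direct test of the difference. Part and clones differ between these responses too. With 2 libraries per xenograft group, no split of these libraries was counted.

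In the other comparisons of part 1 the real grouping was also the only 1 of 35 splits with as many genes. The real counts were 9306 for osimertinib in SAFE clones, 8192 in clones labelled RB1, and 7449 and 8197 for the clones labelled RB1 against SAFE under vehicle and under osimertinib. The highest other split gave 0, 1209, 0 and 0 genes. The split with 1209 genes moves 2 of the 4 clone pairs together, and the 7 other splits that part all 4 pairs gave at most 0 genes. Each other split mixes the compared groups on both sides. A large difference between these groups then widens the spread within the split groups and lowers their counts. For this reason the low counts of the other splits do not exclude chance here either.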

How the results depend on the processing

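The alternatives were planned except the term for the library sets of part 2 that carry foreign transcripts, the fits without RB1 clone 1, the fit between the parts without symbols that have a pseudogene named after them (9632 genes), and gene list tests with the clone block or the term for library sets, which were chosen after seeing the data. Over all alternatives, single named genes were counted as kept in 26031 values, lost the call in 954, gained it in 105 and reversed in 13. Kept values can include a change of sign where neither fit called the gene. Gene lists were counted as kept in 912, lost the call in 173, gained it in 103 and reversed in 0. Kept lists can include opposite directions that were not called by both tests. The cause of a move was not tested unless the construction shows it. At 1.5-fold the interaction step recovered 9.0% of simulated changes. The xenograft libraries are the shallowest, from 19500563 counts.

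The count of interaction genes was 690 with DESeq2, 2768 with the clone block and 629 without RB1 clone 1, against 292. When only the 8 libraries compared were fitted, osimertinib changed 5172 genes in clones labelled RB1 and 12323 in SAFE clones, against 8192 and 9306. Gefitinib against erlotinib gave 123 genes with no filter, 31 with DESeq2, 11 with all 12 libraries of part 2 and 3 with the term for library sets, against 7, so this small count depends on each of these settings. Dacomitinib against gefitinib gave 6277 with the term for library sets. Linked to vehicle, the counts with no filter were 1005 for erlotinib and 1561 for gefitinib, with no part term 2316, 2493 and 12872 for erlotinib, gefitinib and dacomitinib, and with clone 1 alone in part 1, fewer samples, 62, 66 and 4521. Gefitinib gave 992 with DESeq2 and 261 with the term for library sets.

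The retained share of dacomitinib was 0.711 over genes with a 4-fold change, 0.766 as a median of ratios and 0.765 with clones labelled RB1 as the reference, against 0.744. As medians of ratios erlotinib stood at -0.035 and gefitinib at -0.023.

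Reversed values were PGAM1 at 0.03 in SAFE osimertinib with the osimertinib libraries of both parts, and MCM2 at 0.2 between the labels under vehicle without RB1 clone 1. With no part term, SERPINB2 (-1.54), STRA6 (-0.37), CRISPLD2 (-0.26) and HSD17B7 (0.43) reversed for erlotinib, and SERPINB2 (-1.82), RRM2 (-0.4), CNTN1 (-0.39), HSD17B7 (0.69) and ANGPTL4 (0.61) for gefitinib. With the term for library sets COL2A1 (-1.06) and KRT1 (-1.14) reversed in dacomitinib against gefitinib.

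Leaving out 1 library at a time gave 8266 to 8705 genes for osimertinib in SAFE clones, 7303 to 8366 in clones labelled RB1, 6364 to 7781 and 7037 to 8498 between the labels under vehicle and under osimertinib, and 108 (without SAFE vehicle 2) to 503 (without RB1 osimertinib 1) for the interaction. It gave 8224 to 11237 for osimertinib against erlotinib, 8124 to 11585 against gefitinib and 1971 (without dacomitinib 1) to 7280 (without osimertinib 5) against dacomitinib. Ranges were 6908 to 7789 for dacomitinib against erlotinib, 7125 to 7456 against gefitinib, and 0 (without gefitinib 1 or 2) to 24 (without erlotinib 2) for gefitinib against erlotinib. Through osimertinib they were 196 to 2141 for erlotinib and 237 to 3258 for gefitinib, the highest both without osimertinib 5, and 6666 to 8771 for dacomitinib. They were 7265 to 9965 in xenografts, 3907 to 5775 for their difference from culture, 10227 to 12455 for xenograft against culture and 8005 to 9918 between the parts. Where 1 library was left in a group of 2, it was taken to vary like the other groups.

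With the clone block, osimertinib changed 12731 genes in SAFE clones and 11842 in clones labelled RB1. Beyond the lists named in the comparisons, the block moved the estimated-correlation value of RB-E2F regulators in clones labelled RB1 from 0.029 to 0.141. For the interaction it moved that of FOXO genes and of lysosome genes from 0.0412 to 0.264 each, and no other call of a list changed. Replicate numbers do not pair clones of different labels (correlations across genes of -0.08 to 0.16) or libraries of part 2 (-0.30, 0.22, -0.14 and, in xenografts, 0.02). As a block they gave 8308 genes between the labels under vehicle and 47 for gefitinib against erlotinib.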

Other observations

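The tests of single clones, of abundant genes, of foreign transcripts, of depth between the parts, of pseudogene symbols among ribosomal protein genes, of the RB1 transcript and of chromosome medians were chosen only after the result was seen; the others in this part were planned. In the xenografts, changes beyond the cell cycle included 18 of 22 antigen presentation genes up and 1 down under osimertinib (adjusted p = 0.709 with an estimated correlation) and 13 of 23 replication histones up and 3 down (adjusted p = 0.38 with an estimated correlation). Glycolysis genes fell in 13 of 21 (adjusted p = 0.644 with an estimated correlation), and 15 of 28 NF-kB genes fell and 6 rose (adjusted p = 0.709 with an estimated correlation). The scavenger receptor CD36 rose by 4.42 ± 0.41 and the keratin KRT5 by 3.65.

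Epithelial genes were lower in all 4 clones labelled RB1, not in 1 clone alone, since at least 19 of the 25 tested genes of the list lay below every SAFE clone in each clone. The 577 tested neighbours within 1 Mb of the lowered genes had a median difference of -0.019 (quartiles -0.419 and 0.321), with 124 called lower and 102 higher. This argues against loss of most of the regions that hold these genes. A pooled median cannot exclude loss around single genes or losses smaller than 1 Mb. Abundant genes taking the counts is argued against by their lower share in vehicle libraries labelled RB1. There the 20 most abundant genes held at most 9.47% of counts against at least 9.79% in SAFE vehicle libraries. Absence of RB1 and a difference between the founding cells cannot be told apart here, because the RB1 transcript lay below every SAFE vehicle library in only 1 of 4 vehicle libraries labelled RB1 and a frameshift leaves a transcript. Medians of whole chromosomes also differed between the labels, with an SD of 0.154 over 23 chromosomes against at most 0.044 in 1000 random assignments of genes (chromosome 7 -0.324, chromosome 2 -0.279, chromosome 6 0.288, chromosome 11 0.261 and chromosome 5 -0.226, each with the same sign in all 4 clones). Other medians parted the clones labelled RB1 from each other, with chromosome 16 at -0.476, 0.121, -0.032 and 0.207 and chromosome 17 at 0.218, -0.057, -0.216 and -0.049 in clones 1 to 4. A candidate explanation is copy number differences, some shared by the 4 clones labelled RB1 and some of single clones, while the SAFE medians lay within 0.114 of 0.

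Ribosomal protein genes that stood far higher in part 2 under the same inhibitor may reflect reads shared with pseudogenes that were kept in part 2 and dropped in part 1. A difference in depth is argued against by the totals before scaling, where the highest osimertinib culture of part 2 held 0.735 of the lowest SAFE osimertinib culture of part 1, and more ribosomal protein RNA by the share of 77 such genes that were higher by at least 1 in log2, 29.9%. By gene type, 6.8% of protein-coding genes at least 8-fold higher had a pseudogene named after them against 3.3% of the others, which decides nothing at 88 genes (Fisher's exact p = 0.0722). The 8 such genes above 1 CPM in part 1 were all ribosomal protein genes. Of these 75% had a pseudogene symbol in the files against 89.9% of 69 other ribosomal protein genes (Fisher's exact p = 0.234), which decides nothing at 8 genes. Sharing of reads with pseudogenes therefore stays open, as does which setting differed between the parts.

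T cell transcripts (PTPRC 2.65 to 3.72 CPM and CD3E 1.68 to 2 CPM) appeared in erlotinib 2, gefitinib 1 and 2 and osimertinib 5, and cartilage transcripts (COL2A1 26.75 to 119.01 CPM) in the other 4 cultured libraries of part 2. Of the measured markers 33 did not overlap between these 2 sets of 4 libraries, 24 of 27 for T cells and 9 of 18 for cartilage, where chance separates 1.43% of genes. A response to an inhibitor is argued against by erlotinib, whose libraries differed 12.98-fold in the T cell sum. Carry-over of T cell transcripts from the xenografts is argued against by their highest T cell sum, 8.88 CPM against at least 25.62 CPM. Their highest cartilage sum was 34.1 CPM, against at least 69.19 CPM in the cartilage set. KRT5 stood at 805.1 and 1979.15 CPM in xenograft osimertinib libraries, 1.84 to 6.93 CPM in the cartilage set and at most 0.22 CPM in the T cell set. Carry-over of KRT5 was not tested. A candidate source is RNA or reads of other samples handled beside these libraries, a hypothesis found and tested on the same data; cartilage sums of 16.83 to 35.15 CPM in the other set show that the line itself expresses some of that list. The contrast of dacomitinib with gefitinib follows the 2 sets completely.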
